A study of Mus musculus with 2 samples.

How the data were processed

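Polyadenylated RNA was sequenced from the gonadal fat pad, the white adipose depot attached to the gonads, of 8-week-old C57BL/6J mice. There were 2 libraries, which the labels call biological replicates 1 and 2 of 1 group, from separate biosamples of a pool of both sexes. Both carry the same donor identifier, so it is open how many mice stand behind each library. Per the labels, RNA longer than 200 nt was used, and the libraries were strand-specific and read as 76 nt pairs. No condition was compared.

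The deposited gene and transcript tables gave an expected count, which is an estimated number of fragments that need not be whole, for each row. The authors' tables also gave TPM (transcript abundance scaled to a fixed total per library), FPKM (fragments scaled by transcript length and library size) and the posterior mean of each. Per the file headers, the transcript tables added the percent of the gene's TPM carried by each transcript. The accompanying notes name the mouse build mm10 and GENCODE annotation M4. The aligner and the quantifier are not given in the sources used here. Each deposited gene table held 69691 rows, of which 43346 were Ensembl genes, 96 were ERCC spike-in RNAs, 1 was the phiX genome and 26248 carried a numeric identifier and no gene name. The unnamed rows held 0 counts in replicate 1 and 2 counts in replicate 2, phiX held 0 in both, and these rows entered no result. TPM was computed by the authors over all rows, spike-ins included.

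The series also holds deposited tables of splice junctions and of contigs (stretches of continuous read coverage) on the older build mm9, each made over both libraries together. The junction table gave the count of reads across each junction, split in its names into R1 and R2, and an irreproducible discovery rate (IDR), a fraction that is low where replicates rank a feature alike. The deposited contig table gave an RPKM, an IDR fraction and a further score that rose with length and RPKM. The labels do not tie R1 and R2 to the libraries. The junction names also carry flags A and C, whose meaning is not stated in the table. The mm9 coordinates were kept as deposited and were never set against the mm10 tables.

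Gene symbols were matched by Ensembl identifier without its version for 42462 of the 43346 genes, and 884 had no match. Positions, biotypes, transcript names and coding lengths are from GENCODE M21 on mm10, the build of the gene tables. For a transcript of about 2 kb, the floor of 3 fragments came to 0.0402 TPM in replicate 1 and 0.0323 TPM in replicate 2. Floors cover counting error only. In the deposited tables effective length was shorter than length by a median of 216.5 nt in replicate 1 and 223.5 nt in replicate 2 among long rows, and by less in rows shorter than that, so the TPM of transcripts close to that length rested on a very small divisor.

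A gene was called expressed at 1 TPM or more in both libraries. The log2 ratio was that of (TPM + 1), replicate 2 over replicate 1, which understates differences of low genes. A gene counted as over 2-fold apart when its mean expected count was 20 or more and the ratio passed 2 in either direction. Counting error alone was drawn 100 times from Poisson counts with equal expected levels. The libraries were checked for identity by a chi-square statistic on rounded expected counts, over genes with 10 or more counts in sum. There were 42 gene lists, 38 written as symbols and 4 as name patterns. One pattern took the spike-ins, which were described apart. For each of the other 41 lists the median TPM over all measured members, the number expressed and the median log2 ratio of members with a mean of 1 TPM or more were computed. The last was placed among 10000 random lists of equal size, matched on mean level in 20 bins. That percentile describes these libraries and is not a p-value. With 1 group of 2 replicates no test between conditions exists and no p-value was computed.

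The lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule took the 25 genes of highest mean TPM, up to 4 top members per list with textbook members under 1 TPM, and the 10 largest ratios in each direction among genes with a mean count of 100 or more and a mean of 1 TPM or more. It also took a fixed set of isoform genes with the 10 highest genes that had several transcripts at 10 percent or more, and the 5 highest junctions and contigs. Genes named outside it are marked as chosen after their values were seen.

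Alternatives covered other TPM thresholds, posterior mean TPM, FPKM, a pseudocount of 0.1, other count minimums, TMM scaling in edgeR 4.0.16 and DESeq2 1.42.0 size factors on rounded expected counts, removal of mitochondrially encoded genes, IDR limits of 0.1 and 0.01, and each replicate alone. The code of the 2-fold rule was tried on simulated data of 16904 genes with 200 changed, drawn with counting error only, so this does not measure error between biological replicates. It recovered 189 of these at a 4-fold change and 195 at an 8-fold change, and placed 0 unchanged genes over 2-fold. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3.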

Results

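RNA of the gonadal fat pad of adult C57BL/6J mice was measured in 2 libraries of 1 group, biological replicates 1 and 2 by their labels. Expected counts summed to 48206393 in replicate 1 and 55138711 in replicate 2. Values below are TPM in replicate 1 and then replicate 2 unless stated otherwise. With 2 replicates and no second condition, differences between the libraries are described and not tested.

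The first question was which genes the tissue expressed. There were 14303 genes at 1 TPM or more in both libraries, 13235 of them protein-coding by annotation. The 131 expressed genes with a mean of 1000 TPM or more held 43.8% of the TPM of all genes, and the 6000 between 1 and 10 TPM held 2.82%.

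Genes of adipocytes and of the epididymis, the duct in which sperm mature, were among the abundant tissue-specific transcripts. All 20 members of the adipocyte identity list were expressed, with a median of 496.9 and 524.2 TPM. Cfd, which encodes the complement factor adipsin, reached 6724 and 3717 TPM, and Car3, the carbonic anhydrase of adipocytes and muscle, reached 4587 and 5790 TPM. Fabp4, the fatty acid carrier of fat cells, stood at 2869 and 2744 TPM. Lpl, the lipoprotein lipase, stood at 1590 and 1863 TPM. All 16 members of the epididymis list were expressed, with a median of 1287 and 1489 TPM, and in both libraries that median lay above the adipocyte median. Gpx5, a secreted glutathione peroxidase of the epididymis (chromosome 13, 21286429 to 21292731, mm10), was at 9518 and 6082 TPM. The lipocalin genes Lcn8 and Lcn5 were at 7811 and 3137 TPM and at 4251 and 2773 TPM. Spag11b, a defensin-like gene, was at 3128 and 1539 TPM. By share of fragments, which carries no length scaling, the epididymis list held 2.53% and 1.99% of all gene counts and the adipocyte list 2.32% and 2.84%. By that share the order of the lists differed between the libraries, and both measures depend on which genes a list holds.

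**Figure D1:**
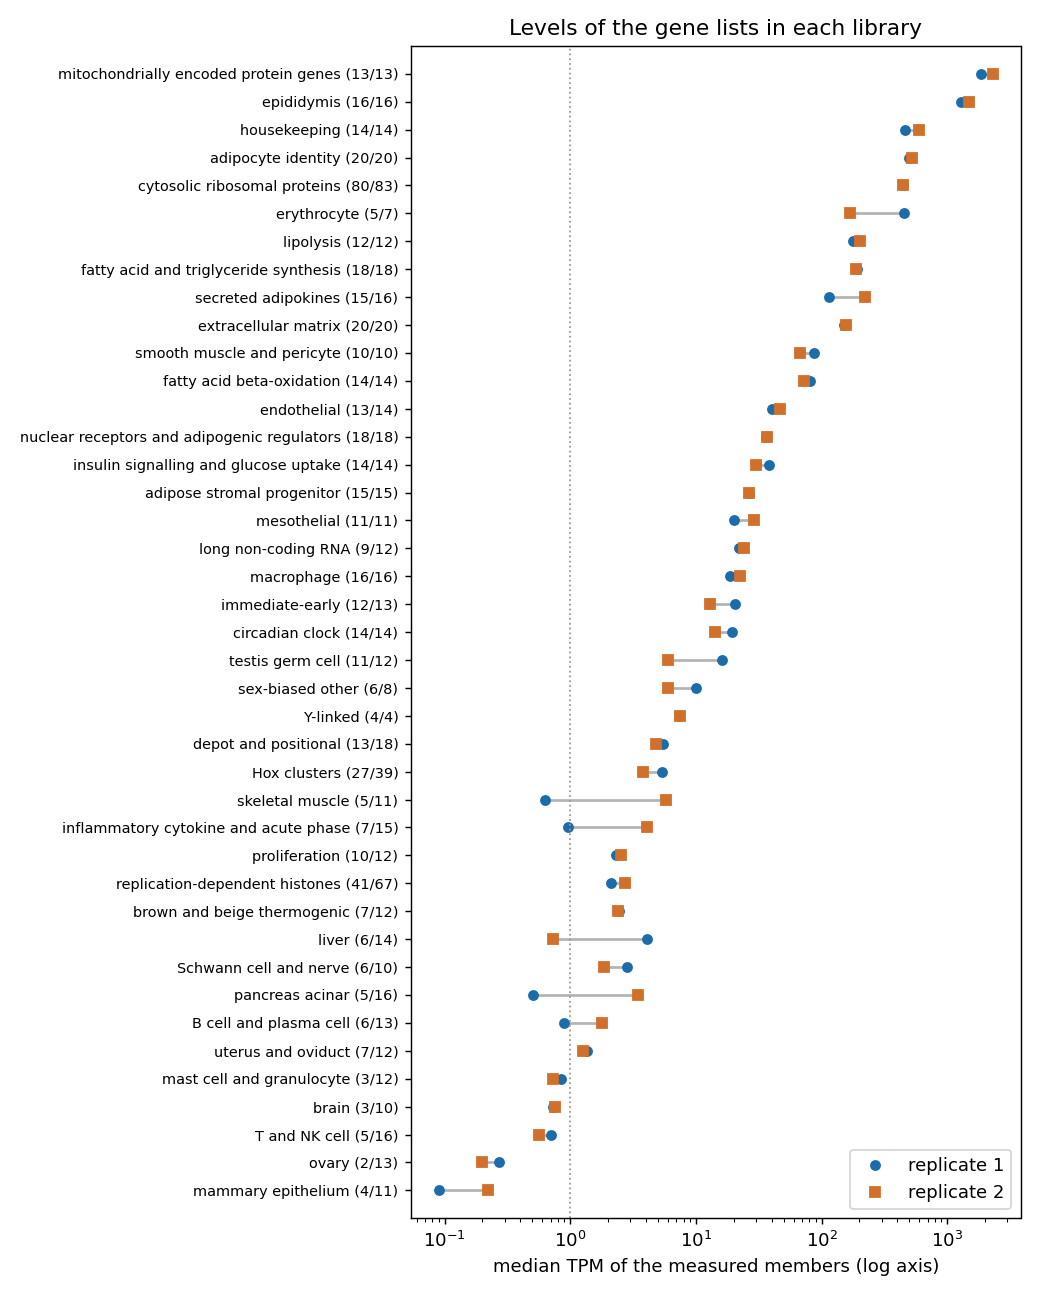
Median TPM of the measured members of each gene list (log axis) in replicate 1 (circles) and replicate 2 (squares), with expressed and measured members in brackets. The epididymis list, at 1287 and 1489 TPM, lies above the adipocyte list, at 496.9 and 524.2 TPM, and the ovary list lies under 1 TPM.

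Most genes of fat synthesis, release and secretion were expressed. The fatty acid and triglyceride synthesis list had 18 of 18 members expressed and a median of 191.0 and 188.0 TPM. It was led by Fasn, the fatty acid synthase, at 1902 and 3140 TPM, and by Scd1, a stearoyl-CoA desaturase, at 2079 and 2234 TPM. Short retained-intron forms carried most of the TPM of Fasn, and its coding form Fasn-201 was at 535.9 and 705.0 TPM. By fragments Scd1 stood above Fasn, at 358086 and 478497 against 219914 and 378071. Dgat2, which makes triglyceride, was at 819.1 and 2155 TPM, and Thrsp, a regulator of lipogenesis, at 435.4 and 1028 TPM. All 12 lipolysis genes were expressed, with a median of 179.3 and 203.0 TPM. Among them, Pnpla2, the adipose triglyceride lipase, was at 948.5 and 816.3 TPM. Plin1, which encodes a protein of the droplet surface, was at 653.7 and 578.2 TPM. The hormone-sensitive lipase gene Lipe was at 501.5 and 473.6 TPM and the beta-3 adrenergic receptor gene Adrb3 at 566.3 and 347.0 TPM. Of the secreted adipokines, 15 of 16 were expressed, with a median of 114.7 and 221.5 TPM. Apoe stood at 3044 and 2406 TPM and Adipoq, which encodes adiponectin, at 767.3 and 1299 TPM. The omentin gene Itln1 was at 0.090 and 0.14 TPM.

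Brown fat genes were low. Ucp1, the uncoupling protein of brown adipocytes, was at 0.21 and 0.45 TPM from 11 and 30 fragments. The thermogenic list had 7 of 12 members expressed and a median of 2.46 and 2.39 TPM. Its highest members were Cox8b at 9.76 and 30.8 TPM, Cox7a1 at 6.72 and 14.6 TPM, Prdm16 at 7.57 and 5.58 TPM and Cidea at 4.19 and 4.97 TPM. Dio2, the deiodinase that activates thyroid hormone, was at 0.15 and 0.69 TPM. The 14 genes of fatty acid beta-oxidation were all expressed, with a median of 81.1 and 72.7 TPM, led by Ech1 at 416.8 and 515.5 TPM, Acaa2 at 101.9 and 119.7 TPM, Etfb at 102.4 and 113.0 TPM and Acads at 87.7 and 116.4 TPM.

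Regulators of fat cells were expressed at moderate levels. All 18 members of the nuclear receptor and adipogenic regulator list were expressed, with a median of 36.1 and 36.7 TPM. They were led by the transcription factor genes Cebpa at 224.9 and 197.5 TPM, Cebpb at 172.7 and 124.6 TPM, Pparg at 67.3 and 88.5 TPM and Nr1h3 at 55.9 and 78.9 TPM. The insulin signalling list had 14 of 14 members expressed and a median of 37.8 and 29.9 TPM. It was led by Cav1, a caveolar coat protein, at 1643 and 2419 TPM. The kinase genes Akt2 and Akt1 were at 117.3 and 133.6 TPM and at 95.9 and 73.0 TPM. The insulin-responsive glucose transporter gene Slc2a4 was at 99.1 and 106.5 TPM.

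Nearly all markers of supporting cell types were expressed, but bulk RNA does not tell which cells or tissue of the pad carried them. The matrix list had all 20 members expressed and a median of 150.3 and 156.7 TPM, led by Sparc at 2991 and 5224 TPM, Mgp at 1328 and 828.3 TPM, Dcn at 430.9 and 399.9 TPM and Col6a1 at 259.2 and 295.8 TPM. The stromal progenitor list had 15 of 15 expressed, at a median of 26.3 and 26.6 TPM, led by Ly6c1 at 220.4 and 280.8 TPM, Col15a1 at 177.6 and 275.0 TPM, Ly6a at 117.3 and 207.1 TPM and Cd24a at 133.0 and 103.4 TPM. Of the endothelial genes, 13 of 14 were expressed, at a median of 40.2 and 46.5 TPM, led by Egfl7 at 262.4 and 340.7 TPM, Eng at 89.3 and 83.8 TPM, Cldn5 at 81.0 and 87.5 TPM and Cdh5 at 75.7 and 70.0 TPM. Prox1, which marks lymphatic endothelium, was at 0.70 and 0.50 TPM. All 10 smooth muscle and pericyte genes were expressed, at a median of 87.4 and 67.3 TPM, with Acta2 at 1098 and 1261 TPM, Actg2 at 1063 and 922.4 TPM, Tagln at 247.1 and 335.7 TPM and Cnn1 at 104.8 and 116.6 TPM. The mesothelial list had 11 of 11 expressed, at a median of 20.2 and 28.8 TPM. Its top members Krt8, Krt18 and Krt19, at 228.7 and 155.6, 213.9 and 144.7, and 174.9 and 138.7 TPM, are keratins shared by other epithelia. The more specific Upk3b stood at 37.3 and 37.9 TPM.

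Among blood and immune cells, macrophage genes were the most complete set. All 16 were expressed, at a median of 18.6 and 22.3 TPM, with Retnla at 248.4 and 638.1 TPM, the lysozyme gene Lyz2 at 281.8 and 337.4 TPM, and the complement genes C1qb and C1qc at 109.7 and 156.2 TPM and at 105.9 and 137.5 TPM. Of the T and NK cell genes, 5 of 16 were expressed, at a median of 0.71 and 0.57 TPM, led by Klrb1c at 59.7 and 22.8 TPM, Gata3 at 22.1 and 11.1 TPM, Il2rb at 3.66 and 3.04 TPM and Nkg7 at 3.12 and 2.01 TPM. The T cell receptor complex genes Cd3e and Cd3d were at 0.55 and 0.41 TPM and at 0.22 and 0.35 TPM. B and plasma cell genes were expressed for 6 of 13, at a median of 0.90 and 1.80 TPM, and Cd74, which other antigen-presenting cells share, was at 656.2 and 613.8 TPM. Ighm was at 237.6 and 902.8 TPM, Igkc at 62.4 and 58.1 TPM and Cd79b at 2.60 and 2.93 TPM, while Ms4a1, which encodes CD20, was at 0.17 and 0.19 TPM. Mast cell and granulocyte genes were expressed for 3 of 12, at a median of 0.85 and 0.73 TPM, led by Kit at 11.5 and 8.30 TPM. Of the Schwann cell and nerve genes 6 of 10 were expressed, at a median of 2.85 and 1.86 TPM, led by Pmp22 at 88.6 and 89.7 TPM and Mbp at 8.18 and 9.54 TPM.

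Sex-linked genes gave a male signal, although the labels describe a pool of both sexes. Xist, the long non-coding RNA of the inactive X chromosome in females, had 18 fragments in replicate 1 and 4 in replicate 2, which came to 0.030 TPM in replicate 1 and was listed at 0 in replicate 2. The 4 Y-linked genes were all expressed, with Eif2s3y at 10.5 and 16.9 TPM, Kdm5d at 7.94 and 8.25 TPM, Ddx3y at 6.70 and 6.73 TPM and Uty at 4.61 and 5.31 TPM. The level of Uty was 76.1% and 75.1% of that of its X-linked partner Kdm6a, a pair chosen after the values were seen, and the level of Ddx3y was 27.8% and 38.7% of that of Ddx3x. The list of other sex-biased genes had 6 of 8 members expressed, at a median of 10.1 and 6.01 TPM, led by Eif2s3x at 38.9 and 36.5 TPM. Of the ovary genes 2 of 13 were expressed, at a median of 0.27 and 0.20 TPM. They were Inha and Inhba, at 34.7 and 25.7 TPM and at 7.18 and 3.48 TPM, which encode inhibin and activin subunits also made outside the ovary. The aromatase gene Cyp19a1 was at 0.010 TPM in both, and Amh at 0.31 and 0.30 TPM. The uterus and oviduct list had 7 of 12 expressed, at a median of 1.35 and 1.28 TPM, led by Pax8 at 113.6 and 70.0 TPM and Esr1 at 27.0 and 17.9 TPM, and the progesterone receptor gene Pgr was at 0.080 and 0.030 TPM. Of the testis germ cell genes 11 of 12 were expressed, at a median of 16.0 and 5.95 TPM. The cells that carried these transcripts were not determined. The protamine genes Prm2 and Prm1, which pack sperm DNA, were at 222.7 and 171.8 TPM and at 89.1 and 38.8 TPM, Tnp2 was at 125.6 and 69.8 TPM and Odf1 at 68.8 and 59.1 TPM.

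Genes of other organs were mostly low. The mammary epithelium list had 4 of 11 expressed, at a median of 0.090 and 0.22 TPM, and these were epithelial genes, Epcam at 111.3 and 65.0 TPM, Krt5 at 38.2 and 27.1 TPM, Krt14 at 32.9 and 32.5 TPM and Krt7 at 16.4 and 17.7 TPM, while the casein gene Csn1s1 was at 0.020 TPM from 1 fragment in each library. The brain list had 3 of 10 expressed, at a median of 0.73 and 0.76 TPM, led by Nrgn at 19.9 and 14.8 TPM, and Snap25 was at 0.070 and 0.060 TPM. Skeletal muscle genes were expressed for 5 of 11, at a median of 0.63 and 5.83 TPM, led by Acta1 at 68.4 and 83.6 TPM and Ckm at 20.3 and 34.8 TPM.

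By TPM, the highest single rows were mostly RNAs of mitochondria and of small non-coding genes. By expected count mt-Co1, Clu and Gpx5 were highest, and mt-Atp8 and Rn7sk were not among the top 25. The 25 genes of highest mean TPM held 21.4% of the TPM of genes in replicate 1 and 25.7% in replicate 2, and the 25 highest by expected count held 12.5% and 12.9% of gene counts. First by TPM stood mt-Atp8 at 42332 and 55187 TPM, from 3741 and 2924 fragments, because its effective length was 2.37 and 1.14 nt. Rn7sk came next at 16863 and 34063 TPM. Also among the 25 were Rn7s2 at 9508 and 13376 TPM and Rn7s1 at 3755 and 13376 TPM. How far the selection of polyadenylated RNA set the levels of Rn7sk, Rn7s1 and Rn7s2 was not measured. The pseudogenes Gm29216 and Gm10222, at 11716 and 16858 TPM and at 6233 and 5139 TPM, lie close together on chromosome 1. Rn7s1 and Rn7s2 are near-identical copies, and pseudogenes share reads with their parents, so the split of these values is uncertain. The mitochondrial genes mt-Co1, mt-Co3, mt-Cytb and mt-Co2 were at 10279 and 16551, 6827 and 12052, 4769 and 4211, and 2170 and 6282 TPM. Gm28661, a pseudogene outside the top 25 that lies near Gm29216, had 56773 and 10307 counts, against 37836 and 134358 for mt-Co2. Whether reads were split between such pseudogenes and mitochondrial genes was not tested, so differences of mitochondrial genes between the libraries are uncertain. Clu, which encodes clusterin, was at 9825 and 6380 TPM. Crip1 was at 10518 and 8336 TPM, Itm2b at 5655 and 4316 TPM, and Lcn2, a lipocalin of acute phase, at 5287 and 2986 TPM. Besides Gpx5 and Lcn8, the top 25 held the beta-defensin genes Defb25 at 6533 and 5298 TPM and Defb48 at 4374 and 4393 TPM, AY761185 at 4287 and 4200 TPM, and Wfdc10, a whey acidic protein family gene, at 4459 and 4016 TPM. Eef1a1 and Rplp1, of the translation machinery, were at 5040 and 4482 TPM and at 4255 and 5473 TPM. Of these 25 genes 5 had an effective length under 100 nt in both libraries, and 11 were also among the 25 highest by counts. All 13 mitochondrially encoded protein genes were expressed, with a median of 1868 and 2304 TPM. All mitochondrial rows held 2.46% of gene counts in replicate 1 and 3.76% in replicate 2. That share leaves out reads placed on pseudogenes.

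Widely used gene families were expressed as follows. The ribosomal protein pattern matched 83 genes, 80 of them expressed, at a median of 446.5 and 443.4 TPM, with Rps12 at 3411 and 3557 TPM, Rps21 at 2813 and 3311 TPM and Rpl13a at 2854 and 2536 TPM. Members with processed pseudogenes share reads with them, so their single values are uncertain. The 14 housekeeping genes were all expressed, at a median of 459.6 and 598.9 TPM, with Gapdh at 2416 and 2722 TPM, Actb at 2826 and 2194 TPM, Rplp0 at 2306 and 1982 TPM and Eef2 at 1762 and 1438 TPM. Of 67 histone genes 41 were expressed, at a median of 2.13 and 2.71 TPM, with Hist2h2aa1 at 698.8 and 627.0 TPM, Hist1h2bc at 366.2 and 406.3 TPM and Hist1h1c at 57.9 and 55.5 TPM. Hist2h2aa1 and Hist2h2aa2 are near-identical copies, and their split is uncertain. How far the selection of polyadenylated RNA set the histone levels was not measured. Of the proliferation genes 10 of 12 were expressed, at a median of 2.33 and 2.54 TPM, with Pcna at 36.8 and 36.8 TPM, Mcm2 at 11.8 and 11.5 TPM and Mki67 at 0.57 and 0.49 TPM. Long non-coding RNAs were expressed for 9 of 12, at a median of 22.0 and 24.2 TPM, with Neat1 at 586.6 and 613.5 TPM, Malat1 at 317.1 and 334.5 TPM, Meg3 at 105.7 and 154.1 TPM and Gas5 at 131.7 and 62.5 TPM. Circadian clock genes were all expressed, 14 of 14, at a median of 19.3 and 14.1 TPM, led by Nr1d1 at 89.7 and 58.8 TPM, Tef at 52.0 and 45.9 TPM, Dbp at 41.5 and 23.8 TPM and Per1 at 31.6 and 19.9 TPM. Hox genes were expressed for 27 of 39, at a median of 5.38 and 3.81 TPM, with Hoxb8 at 194.8 and 105.3 TPM, Hoxb6 at 181.5 and 118.0 TPM, Hoxd4 at 121.9 and 70.4 TPM and Hoxd8 at 66.2 and 33.1 TPM. The depot list had 13 of 18 expressed, at a median of 5.47 and 4.80 TPM, with Hoxb7 at 53.4 and 38.0 TPM and Tcf21, a marker of visceral fat precursors, at 45.8 and 41.6 TPM, while the subcutaneous marker Tbx15 was at 0.010 and 0.14 TPM and Shox2 at 0.12 and 0.070 TPM.

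The second question was how far the replicates differed. Across the 24017 genes above 0 in either library, Pearson's r of log2(TPM + 1) was 0.986 and Spearman's rho was 0.967. Genes are not independent replicates, so these describe the agreement of 2 libraries. The SD of the log2 ratio was 0.40. The chi-square statistic per degree of freedom was 136.1 over 19548 genes, so neither library was a copy of the other. This does not show that the libraries are biological replicates, which rests on the labels. Of 16920 genes with a mean expected count of 20 or more, 457 were over 2-fold apart, 195 higher in replicate 2 and 262 higher in replicate 1. Simulated libraries with equal levels gave a median of 0 such genes and at most 2. The median gene at 1 TPM or more had a log2 ratio of -0.12 on the TPM scale and 0.01 after TMM scaling, under which 228 genes were higher in replicate 2 and 170 higher in replicate 1. Dividing the TPM of replicate 2 by a single factor that brought the median ratio to 1, an alternative chosen after seeing the data, gave 251 and 176, so the split by direction depended on the scaling.

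**Figure D2:**
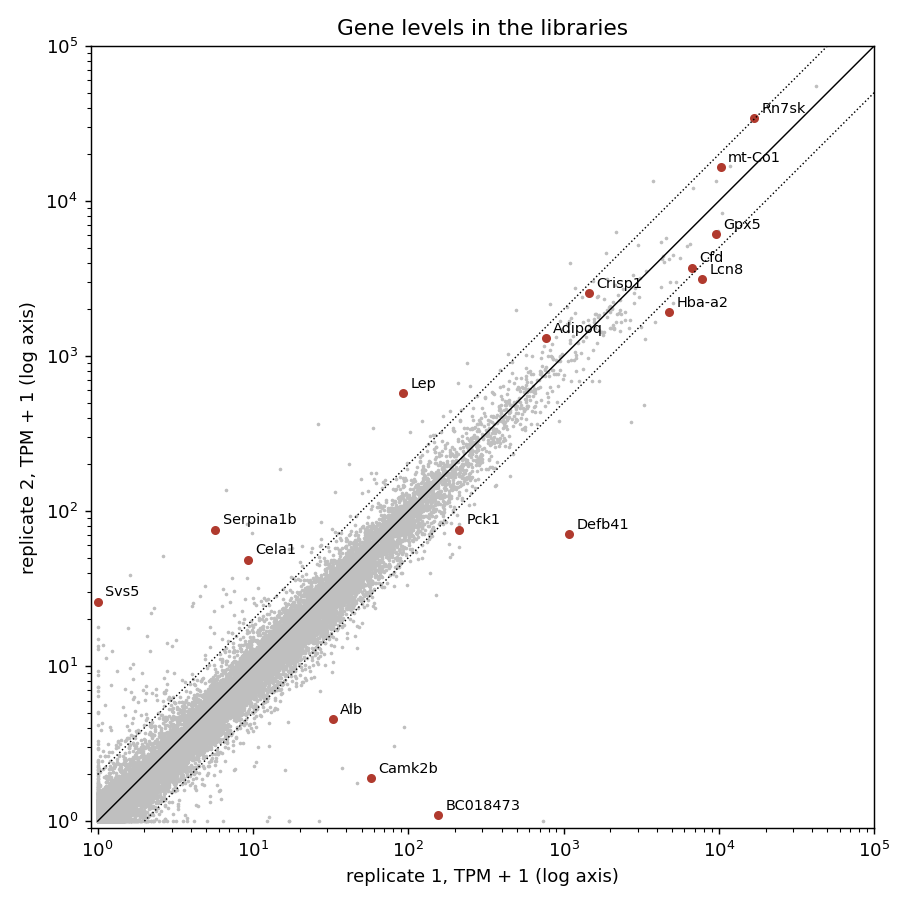
TPM + 1 of each gene above 0 in either library, replicate 1 on the x axis and replicate 2 on the y axis (log axes), with the line of equality and dotted lines at 2-fold. Of the named genes, Gpx5 and Adipoq lie within 2-fold, and Lep, Cela1, Svs5, Alb and Camk2b lie outside.

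Several adipocyte and inflammation genes were higher in replicate 2. Lep, which encodes the satiety hormone leptin, was at 92.1 and 574.8 TPM, a log2 ratio of 2.63 (chromosome 6, 29060220 to 29073877, mm10). Sfrp5, a secreted Wnt antagonist of fat cells, was at 8.84 and 71.2 TPM, and Mogat2, an acylglycerol transferase, at 5.66 and 28.1 TPM. Lep, Sfrp5 and Mogat2 were chosen after their values were seen, as was Pck1, the enzyme of glyceroneogenesis, which went the other way at 211.1 and 74.9 TPM. Of 15 adipokines 10 were higher in replicate 2, with a median log2 ratio of 0.35 and a percentile of 99.96 among random lists, while the list's share of TPM was 1.32% and 1.13%, with Cfd and Apoe lower in replicate 2. For adipocyte identity, 12 of 20 were higher, with a median of 0.17 and a percentile of 98.0. This place outside the random range rested on Lep, since without it, an alternative chosen after seeing the data, the median was 0.11 and the percentile 92.4, within the range, while the adipokines had 0.29 and 99.89. The adipocyte list is not independent of the others, since 12 of its members are also in another list, with Adipoq, Cfd, Lep, Lpl and Retn among the adipokines. For fat synthesis, 11 of 18 were higher, with a median of 0.14 and a percentile of 98.1, and after TMM scaling this percentile was 95.8. In the inflammatory and acute phase list, 7 of 15 members were expressed, at a median of 0.96 and 4.12 TPM, and 8 of the 9 with a mean of 1 TPM or more were higher in replicate 2, with a median of 0.67 and a percentile of 100. They included Hp, haptoglobin, at 1184 and 1889 TPM, Orm1 at 60.6 and 174.8 TPM and the chemokine gene Ccl2 at 3.12 and 24.5 TPM. The exception was Lcn2, its most abundant member, and the list's share of gene counts was 0.402% in replicate 1 and 0.371% in replicate 2. Macrophage and endothelial genes had medians of 0.20 and 0.15 and percentiles of 99.95 and 99.0, with 9 of 16 and 9 of 13 members higher in replicate 2. The thermogenic list had a median of 0.20 and a percentile of 98.8, with 4 of 7 members higher in replicate 2. Histones had 0.20 and 100, with 26 of 48 higher, and a difference in the selection of polyadenylated RNA was not tested. Long non-coding RNAs had 0.27 and 99.5, with 7 of 9 higher, and moved to a percentile of 96.5 after TMM scaling.

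Lists of pancreas, liver, erythrocyte and skeletal muscle genes lay farther apart between the libraries than the adipocyte lists. All 8 pancreas acinar genes with a mean of 1 TPM or more were higher in replicate 2, with a median log2 ratio of 2.19 and a percentile of 100. The digestive protease genes Cela1, Ctrb1 and Cela2a were at 8.32 and 47.5, 3.56 and 27.2, and 2.02 and 12.5 TPM, and Clps was at 1.69 and 7.39 TPM. Of that list 5 of 16 were expressed in both libraries, at a median of 0.51 and 3.47 TPM. All 7 skeletal muscle genes were higher in replicate 2, with a median of 0.70 and a percentile of 100. All 5 erythrocyte genes were higher in replicate 1, with a median of -1.38 and a percentile of 0. The globin genes Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt were at 4804 and 1912, 3346 and 1287, 1680 and 693.7, and 449.5 and 166.9 TPM. Hba-a1 and Hba-a2 are close paralogs, as are Hbb-bs and Hbb-bt, so the split within each pair is uncertain. Of 7 measured erythrocyte genes 5 were expressed, at a median of 449.5 and 166.9 TPM. In the liver list, with 6 of 14 expressed at a median of 4.11 and 0.73 TPM, 7 of 9 were higher in replicate 1, with a median of -1.87 and a percentile of 0. Alb, serum albumin, was at 31.6 and 3.54 TPM and Apoa2 at 15.2 and 1.15 TPM, while the antitrypsin genes Serpina1b and Serpina1a went the other way at 4.73 and 74.8 TPM and at 3.92 and 31.8 TPM. These made the liver list's share of gene counts higher in replicate 2, at 0.00912% and 0.0125%. The Serpina1 genes are close paralogs, and their split is uncertain.

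Epididymal, germ cell and positional genes were mostly higher in replicate 1. Of the 16 epididymis genes 12 were, with a median log2 ratio of -0.54 and a percentile of 0. Lcn8 had a log2 ratio of -1.32, while Crisp1, a sperm-coating protein gene at 1453 and 2545 TPM, had 0.81 and was chosen after its value was seen. All 11 germ cell genes were higher in replicate 1, with a median of -0.53 and a percentile of 0.080. Hox genes had a median of -0.45 and a percentile of 0, with 22 of 28 higher in replicate 1, and the depot list, which shares 12 members with other lists, had -0.47 and 0.16. With all members above 0 the depot list had -0.10 and a percentile of 35.2, within the random range. The immediate-early list, with 12 of 13 expressed at a median of 20.7 and 12.9 TPM, had 9 of 12 genes higher in replicate 1, a median of -0.38 and a percentile of 1.29, which with all members above 0 were -0.29 and 5.76, within the random range. It was led by Egr2 at 298.9 and 217.0 TPM, Dusp1 at 50.5 and 66.0 TPM, Zfp36 at 51.1 and 44.4 TPM and Junb at 34.5 and 27.9 TPM. The brain list had a median of -0.59 and a percentile of 1.23 on 4 genes, and -0.04 and 70.7 with all members above 0, within the random range. For the epididymis, brain, fat synthesis and thermogenic lists the median TPM of all members differed from the median of the member ratios in direction.

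**Figure D3:**
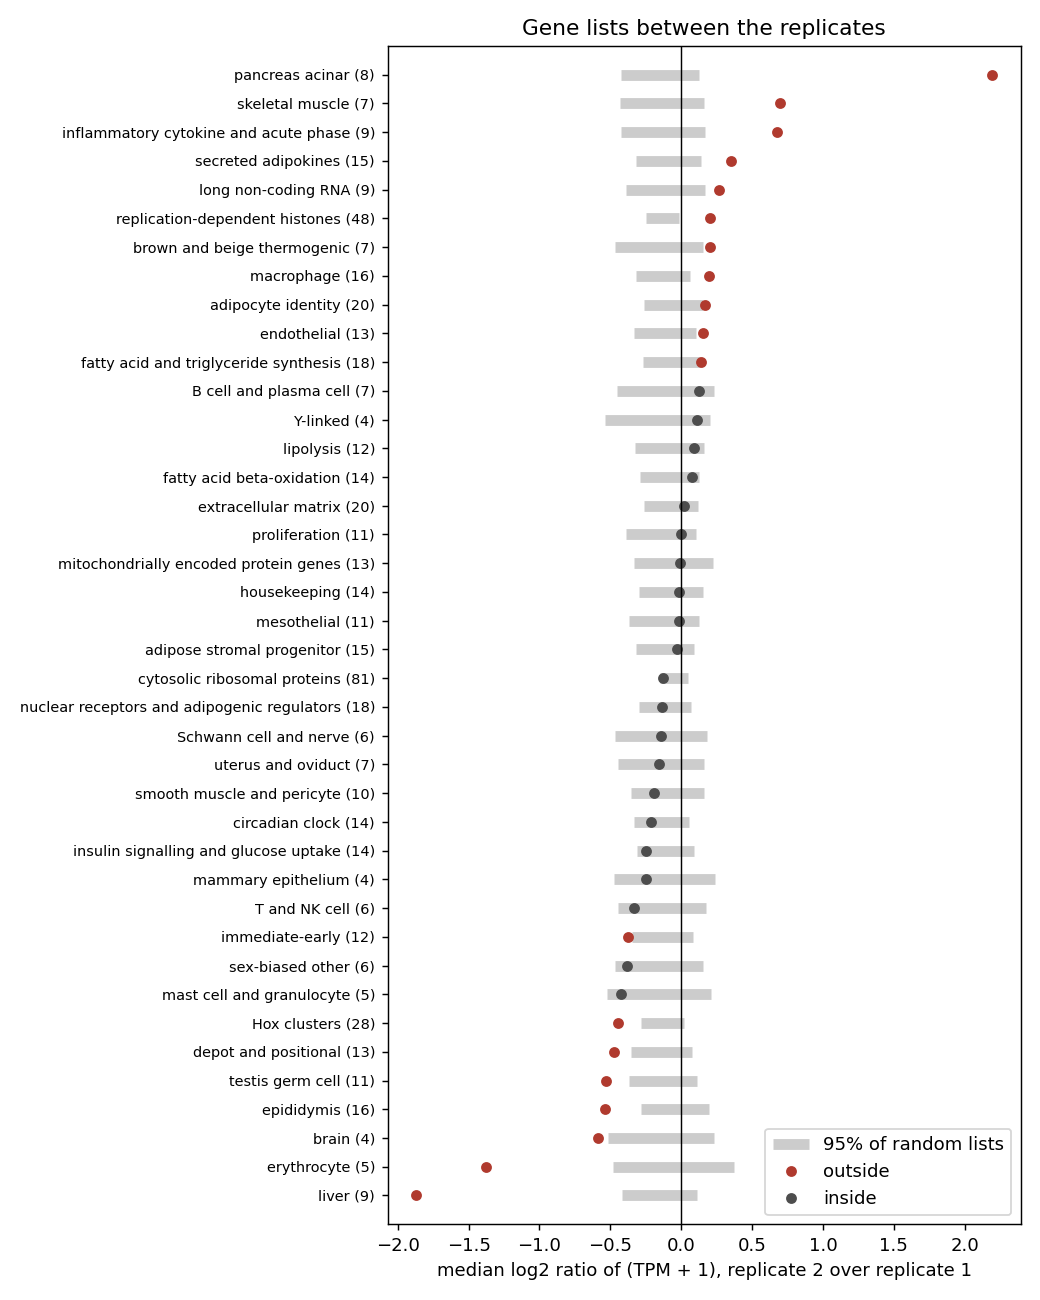
Median log2 ratio of (TPM + 1), replicate 2 over replicate 1, of each list (points, number of genes in brackets) against the central 95% of matched random lists (bars). The pancreas acinar list, at 2.19, and the liver list, at -1.87, lie farthest from their bars.

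The other 21 of 40 lists with a ratio lay within the central range of random lists. The median log2 ratio and percentile were 0.09 and 92.0 for lipolysis, 0.07 and 92.3 for beta-oxidation, -0.25 and 7.79 for insulin signalling, which left the range after TMM scaling at a median of -0.18, -0.03 and 77.5 for stromal progenitors, and 0.02 and 81.2 for matrix. They were -0.02 and 78.6 for mesothelium, -0.19 and 19.5 for smooth muscle, -0.33 and 10.6 for T and NK cells, 0.13 and 92.0 for B cells, -0.43 and 6.95 for mast cells and granulocytes, and -0.14 and 47.5 for Schwann cells. For uterus and oviduct they were -0.16 and 40.8, for mammary epithelium -0.25 and 19.7, for Y-linked genes 0.11 and 93.1, and for other sex-biased genes -0.38 and 6.59. Clock genes had -0.21 and 19.6, proliferation genes 0.00 and 87.7, mitochondrial genes -0.01 and 59.3, housekeeping genes -0.01 and 68.9, regulators -0.14 and 34.4, and ribosomal proteins -0.13 and 5.32. The median levels of the beta-oxidation, stromal progenitor, mesothelial, mammary, mitochondrial, housekeeping and regulator lists also differed in direction from these ratios. The median ratios of the stromal progenitor, mesothelial, housekeeping and ribosomal protein lists were above 0 after TMM scaling. The ovary list had too few genes at 1 TPM for a ratio.

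Single genes farthest apart included genes of the seminal vesicle, a male accessory gland. Svs5 and Svs4, seminal vesicle secretory protein genes, had 0 fragments in replicate 1 and 463 and 282 in replicate 2, at 25.05 and 11.96 TPM. Against a floor of 3 fragments in replicate 1 they were at least 89.5-fold and 76.5-fold higher in replicate 2, and the kallikrein gene Klk1b22, at 12.6 TPM, at least 99.6-fold. Slc7a15, an amino acid transporter family gene, was at 1.65 and 50.5 TPM, and the non-coding 1700047G03Rik at 13.8 and 187.0 TPM. In the other direction stood BC018473, annotated as antisense, at 154.9 and 0.090 TPM, and the kinase gene Camk2b at 56.2 and 0.90 TPM. Defb41 was at 1085 and 70.0 TPM from similar counts of 926 and 809, since its effective length was 22.9 nt in replicate 1 and 243.6 nt in replicate 2. Of these 20 genes 9 were pseudogenes by annotation, whose reads can come from a near-identical parent. These were Gm14165, Gm9625, Gm8730 and Rplp0-ps1, higher in replicate 2, and Gm6969, Gm12616, Gm10182, Gm10925 and Gm28661, higher in replicate 1. Eno1b, at 92.3 and 3.05 TPM, is close in sequence to Eno1 and is uncertain for the same reason. Among annotated pseudogenes 13.0% of 453 were over 2-fold apart, against 2.33% of 15273 protein-coding genes.

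Most genes had the same leading transcript in both libraries. Of 10345 genes with a mean of 1 TPM or more and at least 2 transcripts, 9061, or 87.6%, did. Shares are of TPM, which scales fragments by transcript length. Pparg-201, which encodes 505 residues, carried 91.8% and 93.0% of Pparg, and Pparg-202, which encodes 475 residues, carried 8.25% in replicate 1 and 7% in replicate 2. The longer form is the one known from fat cells. Pkm-201, with the later of the alternative exons (chromosome 9, 59675568 to 59675734), carried 88.6% and 83.8% of the pyruvate kinase gene Pkm, and Pkm-202, with the earlier exon (59675029 to 59675195), carried 11.4% and 16.2%. Adipoq-201 carried 99.7% and 99.6% of Adipoq, Lpin1-201 93.5% and 93.5% of Lpin1, and Mknk2-201 100% of Mknk2. The share of Gnas-208 was 80.2% and 63.2%, and that of the non-coding Gnas-221 was 1.79% and 14.1%. For Insr, Insr-201 carried 57.6% and 55.8% and the retained-intron form Insr-202 the rest, from 5034 and 4102 fragments against 591 and 516. Leading shares were 45.0% and 44.6% for Lmna-203, 30.8% and 30.7% for Srebf1-203, 28.3% and 39.4% for Vegfa-203, a short form with fewer fragments than Vegfa-202, and 44.9% and 38.8% for Fn1-203. Ppargc1a, at 2.12 and 2.01 TPM, had Ppargc1a-203 first in replicate 1 with 38.9% and Ppargc1a-201 first in replicate 2 with 44.5%. Among the 10 highest genes with several transcripts, Eef1a1-201 carried 80.3% and 80.0%, Actb-201 75.99% and 86.3%, Mfge8-202 84.2% and 81.7%, Car3-201 76.9% and 63.0%, Ftl1-201 72.9% and 56.0%, Gapdh-203 53.1% and 58.5% and Apoe-209 54.4% and 43.0%. By this share short retained-intron forms led Fasn, with 38.8% and 42.8% for Fasn-202, and in replicate 1 Sparc, with 36.2% and 33.8% for Sparc-205. By fragments the longer coding forms led, with 187247 and 306567 for Fasn-201 against 15020 and 33621 for Fasn-202. Gpx5-201 carried 19.2% and 31.8% of Gpx5, and the rest went to a transcript absent from the later annotation.

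Spike-in RNAs tracked each other closely. Of 96 ERCC rows 71 had fragments in both libraries, and all 96 together held 3.41% of TPM in replicate 1 and 2.53% in replicate 2. Across 78 detected rows Spearman's rho was 0.980, and of the 39 with a mean count of 100 or more 37 were lower in replicate 2, with a median log2 ratio of -0.42.

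On mm9, the deposited junction table listed 515046 junctions with 40782144 reads. Reads in R1 and R2 came to 19172220 and 21609924, and their log2 counts had a Pearson's r of 0.892 and a Spearman's rho of 0.506 across junctions. Of all junctions 45.96% had a single read, which falls in R1 or R2 only, so the counts cannot agree there. Across the 59787 junctions counted at 100 reads Pearson's r was 0.902. Junctions with flag A at 1 were 33.9% of all and held 95.5% of reads. An IDR of 0.1 or less was met by 80.4% of the 174017 junctions with both flags at 1, and by 2.21% of the 204346 with both at 0, of which 78.6% had a single read. The highest junction, on chromosome 12 from 114391587 to 114391665, had 159258 reads. It was followed by junctions on chromosome 14 from 66598718 to 66599690 with 140790 reads, on chromosome 10 from 79354358 to 79354447 with 126474, on chromosome 14 from 73765670 to 73766127 with 94805, and on chromosome 12 from 86101843 to 86106226 with 94687. The contig table listed 880859 contigs over 315.1 Mb, of which 416414 had an IDR of 0.1 or less. These held 99.3% of the sum of its further score, which is not named there and was read as coverage. The authors' highest RPKM was 12600, on chromosome 16 from 11143991 to 11144422. The next were 5020 on chromosome 9 from 110183743 to 110183886, 3940 on chromosome 3 from 5860318 to 5860829, 3660 on chromosome 9 from 78023099 to 78023440 and 3600 on chromosome 14 from 66594235 to 66595082.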

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

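The alternatives that keep genes of effective length 100 nt or more, leave out pseudogenes or Lep, use counts per library size without TMM factors or rescale TPM by a single factor were chosen after seeing the data. The number of expressed genes ranged from 10223 to 15715 over the thresholds and posterior mean TPM, and from 14640 to 14982 with 1 replicate. The count of genes over 2-fold apart was 457, 398 after TMM or DESeq2 scaling, 545 with no filter on counts, 363 at a mean count of 100 or more, 398 without pseudogenes, 443 without short genes, 407 without TMM factors, 427 with TPM rescaled and 1072 with a pseudocount of 0.1, which lets low genes pass. The share higher in replicate 2 was 42.7%, 57.3% after TMM scaling, 59.0% with DESeq2 size factors, 52.8% without TMM factors, 58.8% with TPM rescaled and 33.6% with the lower pseudocount. Pearson's r was 0.976 with that pseudocount, 0.972 for genes at 1 TPM or more, 0.987 for posterior mean TPM and 0.986 for FPKM. The mean share of the top 25 genes, 23.6%, was 18.9% without mitochondrial genes, 12.7% by expected counts and 18.96% without genes of short effective length, and 21.4% to 25.7% with 1 replicate. Of 120 list ratios under alternatives fixed beforehand, 114 stayed on the same side of the random range, 5 fell inside it, 1 left it and 0 changed sign among those outside it. Lists outside the range numbered 19, and 16 to 19 under alternatives. With posterior mean TPM or without mitochondrial genes, 57 list medians stayed within the spread of the replicates and 24 did not. Lists with a median of 10 TPM or more numbered 22, and 21 to 23 under alternatives and with 1 replicate. The median share of the leading transcript was 68.7%, 65.2% by posterior mean, 67.3% for genes at 10 TPM or more and 68.9% to 69.1% with 1 replicate, and 5615 genes of the last filter kept 1 leading transcript in both libraries because fewer genes entered. Junctions numbered 164045 at an IDR of 0.1, 134727 at 0.01 and 144644 with 10 or more reads, and contigs 416414 and 253593 at the same IDR limits, by construction of the filters. For other moves the cause was not tested. Depth limits genes near 0.0402 TPM, where 3 fragments set the value.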

Other observations

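All tests in this part were chosen after the results were seen. Beta-defensin genes encode antimicrobial peptides of epithelia. Of 42 measured genes named Defb with a number, 30 were at 1 TPM or more in both libraries and 17 at 100 TPM or more, 14 of these with an effective length of 100 nt or more. Together the 42 held 0.370% of gene counts in replicate 1 and 0.372% in replicate 2. Another group was genes of seminal vesicle secretion and kallikrein genes. Of 10 such genes with a mean count of 20 or more, all 10 were higher in replicate 2, but the group was chosen after its values were seen and includes Svs5, Svs4 and Klk1b22, which prompted the choice. Svs1, Svs2, Svs3a, Svs4, Svs5 and Klk1b22 had 0 fragments in replicate 1. They passed the filter through replicate 2 alone, so their direction was fixed by it. Other members of the group included Klk1b5 at 4.04 and 4.54 TPM and Klk1b27 at 1.21 and 20.9 TPM. Svs1 was at 0 and 5.87 TPM, at least 186.9-fold higher by the floor of 3 fragments.

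Xist was near 0 and Y-linked genes were expressed in both libraries, although the labels describe a pool of sexes. The row for Xist had an effective length of 17549 nt on average, and Neat1 and Malat1 stood at 317.1 TPM or more, so a row that could not be counted is argued against. A sizeable female part is argued against as well, since the higher Xist level was 0.030 TPM. The lowest Y-linked value, 4.61 TPM, shows male tissue but would also be met in a pool of sexes. Tissue of male mice only therefore cannot be told apart from a pool with a female part too small to reach these Xist counts, and the design names no groups by sex to compare.

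Epididymal genes were among the most abundant transcripts. Length scaling of short transcripts is argued against, since the list held 2.26% of gene counts on average, where length plays no part. Epididymal tissue in the dissected pad is a candidate source that stays open. The count of 16 of 16 genes at 100 TPM or more in both libraries, with Gpx5 at 9518 and 6082 TPM, restates the pattern. No other test of it was run. Defb25, at 6533 and 5298 TPM, and Defb48, at 4374 and 4393 TPM, are beta-defensin genes outside the list. They were named for their high level, and their source was not tested either. None of the 16 genes of the epididymis list is in another list of the study, but how many fat tissue itself expresses was not measured. The list lay lower in replicate 2 than random lists did, at a median log2 ratio of -0.54, but a single share that differs cannot be told apart from differences of single genes, since members ran from -1.32 for Lcn8 to 0.81 for Crisp1, with an SD of 0.60 at percentile 77.2 among random sets of genes at 100 TPM or more.

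Lep was higher in replicate 2 by a log2 ratio of 2.63. A larger adipocyte share is argued against as the whole cause, since the other 19 adipocyte genes had a median log2 ratio of 0.11 with an SD of 0.48 and the highest was 0.98. Scaling of the libraries is argued against, since the log2 ratio of Lep after TMM scaling was 2.79. Feeding state cannot be told apart from other differences between the biosamples, since the labels do not record it and the fasting-induced genes Pck1 and Angptl4, both chosen after their values were seen, had log2 ratios of -1.48 and 1.14, in opposite directions.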
